A study of Drosophila melanogaster with 6 samples.

How the data were processed

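Chromatin from CbxHm/+ wing discs was fixed with formaldehyde, sheared to fragments of about 500 bp and precipitated with an in-house polyclonal antibody against Ubx, per the labels' protocols. The DNA was amplified by ligation-mediated PCR before labelling, per the labels' protocols, so the ratios are those of amplified DNA. Per the labels, Ubx precipitate was labelled with Cy5 and mock precipitate with Cy3 on all 6 arrays. There was no dye swap, so a dye effect of a probe is part of its ratio.

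The authors deposited 1 scanner file per array with spot intensity values in both channels, and a table of log2 ratios. The intensities were extracted with Agilent Feature Extraction 10.5.1.1, per the file headers, while the submitters' processing notes name version 10.2 and the dm3 build. Per the file headers the processed signals were background-subtracted and scaled with 1 linear dye factor per channel, with no lowess step. Spots not significantly above background carry a floor value in place of a signal. Both channels held such floor values at 25.1% to 26.5% of the probes in replicate 1, 29.6% to 30.1% in replicate 2 and 6.20% to 6.63% in replicate 3. The deposited log2 table equalled the scanner's log10 ratio of Cy5 over Cy3 rescaled to base 2, with no difference above 5.0e-10, and its median was 0 on every array. Its scale and direction are therefore known. The log2 ratio of the processed signals had a median of -0.49 and -0.58 on the arrays of replicate 1. A median of 0 in the table thus does not show that it is centred as the values analysed are.

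The value analysed was the log2 of the Cy5 over the Cy3 processed signal, with each array centred on its median over genomic probes. Control spots and spots marked as outliers (98 to 362 per array) were left out, and 17 probes of the first slide and 32 of the second had no position. After centring, the mean log2 ratio over probes was 0.39 to 0.45 in replicate 1, against -0.06 to 0.07 in the others. The slides carry different probes and were joined into 1 column per replicate. A window was centred on each probe and averaged, per replicate, the probes whose centres lay within 500 bp, with at least 3 probes, which gave 469196 windows with a median of 4 probes each. Start and end of a region are the centres of its first and last window.

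The planned test was the limma fit of an intercept to the 3 replicates with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment. An enriched window needed an adjusted p under 0.05, a mean log2 ratio of at least 0.5 and a ratio above 0 in each replicate, and a depleted window the mirror of this. Windows within 1000 bp were merged, and a region needed at least 2. The null set circularly shifted replicates 2 and 3 along each chromosome in 20 draws. Analyses ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

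These tests, thresholds and most alternatives were set before the data were examined. The rule for naming took the 15 regions with the highest mean log2 ratio of their top window, the 5 depleted regions with the lowest, and, where none passed, the 5 windows with the largest absolute moderated t. After the limma fit had called no window, windows in the top 1% of each replicate's own values were taken as shared windows, and the naming rule was carried over to the regions merged from them. The analysis of neighbouring regions, of left-out replicates, of chromosome arms and of 50 kb windows was also chosen after the data were seen.

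The scripts were tested on simulated data made from the real log ratios with replicates 2 and 3 shifted and 200 sites raised, over 469092 windows. Where 4 was added to the log2 ratio of every replicate, limma with 3 replicates found 0 of 50 sites, limma without replicate 1 found 50, and the top 1% rule found 43. Where 2 was added to each, these counts were 0, 47 and 8 of 50, and where 1 was added to each they were 0, 1 and 0. Where 4, 1 and 2 were added to replicates 1, 2 and 3, they were 0, 7 and 34 of 50. Outside the raised sites the limma fit made 0 calls, the fit without replicate 1 made 1 and the top 1% rule made 1. In this simulation the fit with all 3 replicates thus called no site of any size added.

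The alternatives were a normexp background correction, loess within arrays, centring on the mode, scaling of the replicates to one MAD, the deposited log2 table, a filter on the mock signal, other window widths, thresholds and merging distances, eBayes with trend and robust options, a separate fit per slide, and leaving out each replicate. Normexp was run on the median spot signals, in place of the mean signals that had been planned. Each replicate was scanned on its own day, so a scan batch holds 1 replicate and gives no value within batch. Gene names need an annotation of the dm3 build, and the gene table at hand describes another assembly. Promoters, genes near regions, gene lists, position classes and motifs were therefore not analysed here, nor was a correction for probe GC content, for which the median of each probe length was subtracted instead as an alternative chosen after the data were seen.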

Results

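Binding of Ultrabithorax (Ubx), the Hox transcription factor that gives the haltere its identity, was measured in wing imaginal discs of third-instar Drosophila melanogaster larvae heterozygous for CbxHm. Contrabithorax (Cbx) alleles are gain-of-function alleles of Ubx that express the protein in the wing disc, where it is normally absent from the wing pouch. Chromatin was immunoprecipitated with an antibody against the N-terminal part of Ubx, and each precipitate was hybridised together with a mock precipitate of the same tissue to a tiling array of the whole genome. The array comes on 2 slides with different probes, so 3 biological replicates gave 6 arrays, all with the Ubx precipitate in Cy5 and the mock in Cy3. The first slide held 237699 genomic probes and the second 237696. All samples belong to 1 group, and the comparison the design implies is Ubx precipitate over mock at each position, which asks where Ubx sits on the genome of these discs.

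The replicates differed in signal. In replicate 3, 68.9% to 69.4% of the probes were well above background in the mock channel, against 44.3% to 46.9% in replicate 1 and 35.3% to 35.4% in replicate 2. The standard deviation of the log2 ratio over probes was 1.94 to 2.00 in replicate 1, 0.45 to 0.47 in replicate 2 and 0.80 in replicate 3. Replicate 1 also varied most with probe length. Its probes of 45 to 59 nt, 31.5% of all, had a median log2 ratio of 0.44 against -0.05 for those of 60 nt. These medians were 0.08 and 0.00 in replicate 2, and 0.08 and -0.03 in replicate 3. The number of arrays limits the precision of every value below. Positions are those of the dm3 build, and the regions are given by position alone, since no gene annotation of that build was used here.

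Ubx precipitate exceeded mock at 69 narrow regions that lay in the top 1% of 1 kb windows of each of the 3 replicates. This ranking within each replicate was chosen after the planned test, described further on, had called no window. The strongest was 3L 10730127 to 10730371, with a log2 ratio of Ubx precipitate to mock of 3.49 ± 1.28 (SD, n = 3). Next came 3R 16849206 to 16849555 at 3.28 ± 1.86, 2R 18910052 to 18910944 at 3.21 ± 2.21, 3R 12060992 to 12061575 at 3.19 ± 1.85, and the single region of chromosome 4, 528644 to 529121, at 3.08 ± 1.62. Over the 69 regions the mean log2 ratio of the top window ran from 2.01 to 3.49 with a median of 2.65.

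The other 10 of the 15 strongest shared regions had mean log2 ratios between 2.93 and 3.08. On X they were 2189651 to 2190235 at 3.08 ± 2.90, 2541610 to 2542089 at 3.05 ± 2.63, and 12149009 to 12149442 at 2.94 ± 2.01. On 3L they were 22437655 to 22437894 at 3.04 ± 2.74, 14627787 to 14628222 at 3.04 ± 1.53, and 12608952 to 12609427 at 2.93 ± 2.28. On 3R they were 19968445 to 19968934 at 3.06 ± 1.69 and 12589475 to 12589969 at 2.95 ± 2.27. The last ones were 2R 15837819 to 15838283 at 2.99 ± 1.89 and 2L 11046509 to 11046874 at 2.95 ± 1.90.

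**Figure D1:**
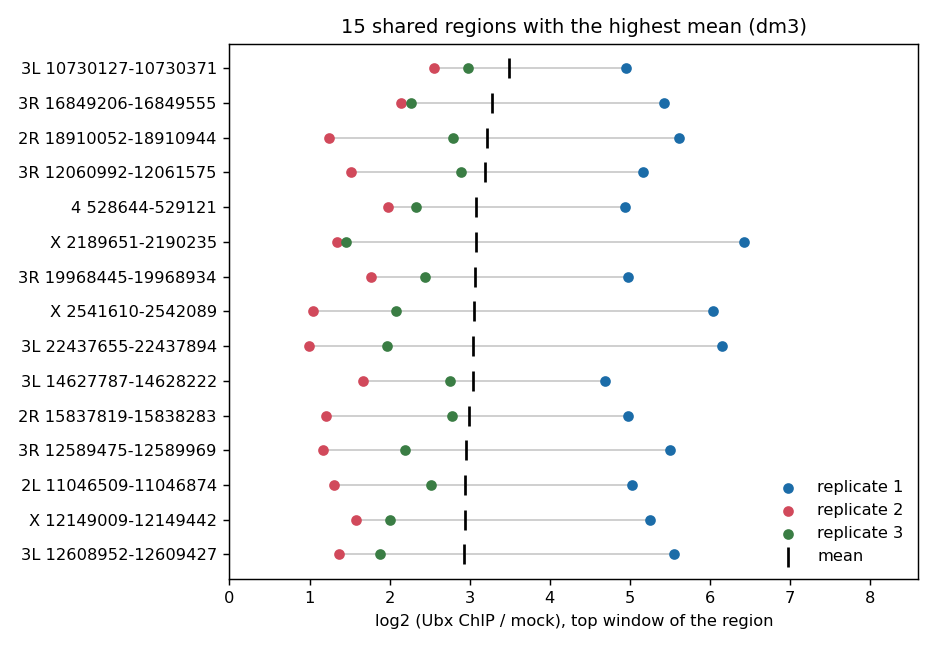
Log2 ratio of Ubx precipitate over mock in the top window of the 15 shared regions with the highest mean. Points are the 3 replicates, bars their mean, and rows are regions by dm3 position. Every replicate lies above 0 at every region, with replicate 1 highest in each.

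Each replicate had to rank high at these regions, so all ratios were above 0, and the spread lay in their size. Across the 69 regions the top window's log2 ratio ran from 3.51 to 6.42 in replicate 1, from 0.82 to 2.55 in replicate 2 and from 1.46 to 3.38 in replicate 3. A window entered the top 1% at 3.44, 0.78 and 1.43 in these replicates. Because the regions are ordered by the mean, their order and size rest mostly on replicate 1. Without it the means of the 15 strongest regions ran from 1.40 to 2.77, and those of X 2189651 to 2190235, X 2541610 to 2542089 and 3L 22437655 to 22437894 became 1.40, 1.56 and 1.48. The median of the Ubx channel over the shared regions lay at percentile 99.3, 80.4 and 99.4 of all windows in replicates 1, 2 and 3. The mock channel lay at percentile 40.2, 44.4 and 62.6. Choosing regions by the ratio favours a bright Ubx channel and a dim mock, so these percentiles are no separate evidence.

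There were 248 shared windows among 469196, against 0.469 expected if the replicates were unrelated. They formed 125 clusters, of which 56 were single windows and were left out of the regions. When replicates 2 and 3 were shifted along each chromosome, which keeps the local structure of each, 20 draws gave 4 shared windows at most. The bottom 1% of all 3 replicates shared 3 windows. These 3 windows, none of which had a second one beside it, were centred at 2L 1633748, 2L 7626476 and 3R 10871589, with mean log2 ratios of -1.40 ± 0.90, -1.88 ± 1.63 and -1.38 ± 0.85 (SD, n = 3). The shared regions spanned a median of 396 bp between the first and last window centre.

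**Figure D2:**
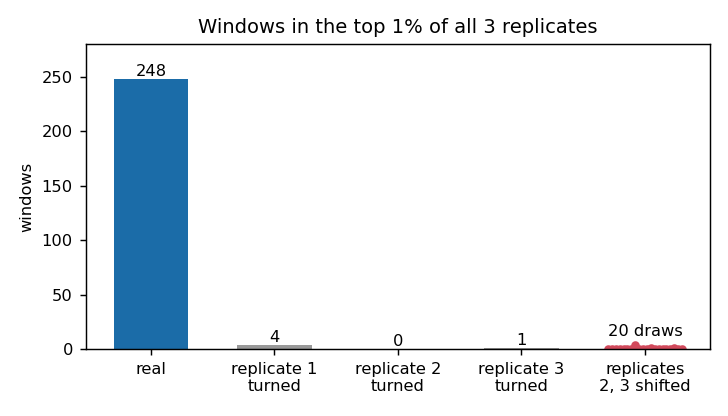
Number of 1 kb windows in the top 1% of all 3 replicates. The first bar is the real orientation with 248 windows, the next 3 bars have the ratio of 1 replicate turned, with 4, 0 and 1 windows, and the points are 20 draws with replicates 2 and 3 shifted along the chromosomes, none above 4.

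Regions picked in 2 replicates were also high in the replicate left out of the choice. The 269 regions picked in replicates 2 and 3 had a log2 ratio of 2.57 ± 1.60 (SD over regions) in replicate 1, against 0.42 over all windows, and 246 of them, or 91.4%, lay above the median of that replicate. For the 136 regions picked in replicates 1 and 3, replicate 2 gave 0.86 ± 0.47 against 0.06, with 133 above its median. For the 103 regions picked in replicates 1 and 2, replicate 3 gave 1.66 ± 0.86 against -0.02, with 98 above its median. The rise in the left-out replicate was highest beside the top window. In successive bins of 500 bp to the right of the top window, and relative to the mean of all probes, it was 2.13, 0.70 and 0.41 in replicate 1, 0.88, 0.15 and 0.16 in replicate 2, and 1.78, 0.78 and 0.49 in replicate 3. In the last of these bins, 4500 to 5000 bp away, it was 0.37, 0.04 and 0.30 in replicates 1, 2 and 3, and at the same distance to the left 0.06, 0.08 and 0.13.

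**Figure D3:**
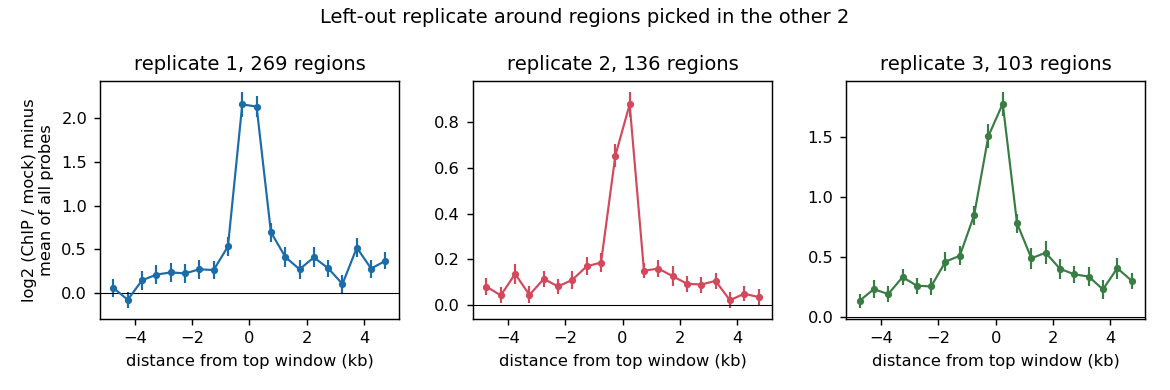
Log2 ratio of the left-out replicate, minus its mean over all probes, by distance in kb from the top window of regions picked in the other replicates. Points are means over regions in bins of 500 bp and bars their standard error. All 3 profiles peak in the bins beside the centre, at up to 2.16 in replicate 1, 0.88 in replicate 2 and 1.78 in replicate 3.

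Some shared regions lay close together. Of the 69 regions, 15 fell into 6 groups whose neighbours were within 50 kb. On 3R, 3 regions between 13525812 and 13530098 had mean log2 ratios of 2.71 ± 2.06, 2.65 ± 2.25 and 2.70 ± 1.18 (SD, n = 3). Also on 3R, the region from 12060992 to 12061575 had a neighbour at 12057140 to 12057303 with 2.76 ± 1.51. On 2L, 3 regions between 669643 and 715521 reached 2.42 ± 1.58, 2.18 ± 1.38 and 2.74 ± 1.77, and on 2R, 3 regions between 11991761 and 12041785 reached 2.27 ± 1.36, 2.39 ± 1.34 and 2.25 ± 1.58. The other groups were pairs, at 2R 15837819 to 15857623 and at X 2028885 to 2052970. These 9 neighbouring pairs compare with 2.01 on average, and 8 at most, in 10000 random placements on the same chromosomes (one-sided permutation p = 0.0001, the smallest these placements can give). Merging within 2000 bp, which joins the closest of them, left 66 regions and 6 neighbouring pairs, against 1.79 on average and 9 at most (one-sided permutation p = 0.0081).

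**Figure D4:**
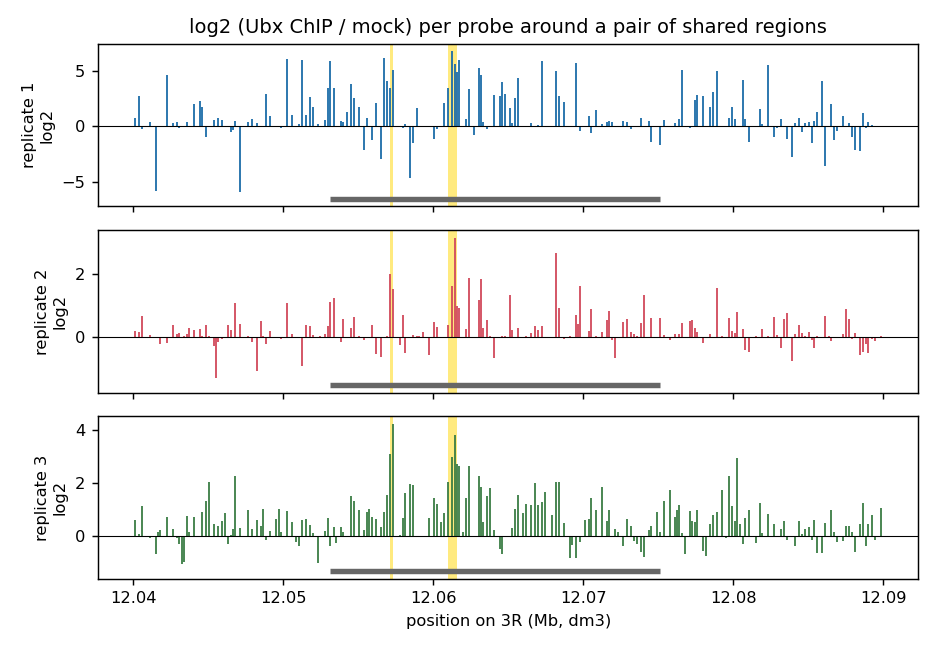
Log2 ratio of Ubx precipitate over mock of each probe on 3R in dm3 coordinates, 1 panel per replicate. Shading marks the shared regions at 12057140 to 12057303 and 12060992 to 12061575. The grey bar spans 12053098 to 12075123, a stretch merged within 25000 bp from window centres whose 50 kb means were in the top 1% of all 3 replicates. Centres between those can fall outside the top 1%.

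The shared regions were spread over the chromosome arms about as the tested windows were. Chromosome arm 3R held 20 of the 69 regions where 16.4 would follow from its windows, 3L held 18 against 13.7, X held 13 against 12.3, 2L held 9 against 13.1, 2R held 8 against 11.7, and chromosome 4 held 1 against 0.55. The heterochromatic, unplaced, Y and mitochondrial sequences held 0 against 1.17. No arm or class passed an exact two-sided binomial test with Benjamini-Hochberg adjustment over the 7 classes, the smallest adjusted p being 0.564.

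The planned test set the mean of each window against the spread between the replicates. With limma and Benjamini-Hochberg adjustment it called 0 enriched and 0 depleted windows, hence 0 enriched regions, and the smallest adjusted p was 0.809. At an unadjusted p under 0.05, 13859 windows were above 0 and 1536 below, against a mean of 4433 above and 610 below in the 20 shifted draws. Single probes gave 0 enriched probes too, with 7528 above 0 and 2123 below at an unadjusted p under 0.05. That balance moved with the processing. The deposited log2 table, taken without further centring, gave 11235 windows above 0 and 3531 below, and 6040 probes above and 6169 below. Normexp gave 23056 windows above and 1 below, and 19826 probes above and 0 below. The 5 windows with the largest absolute moderated t, none of which passed, were all above 0. They were centred at X 2346941 with a log2 ratio of 2.61 ± 0.30, 2L 11806860 with 2.22 ± 0.19, X 6671159 with 2.37 ± 0.39, 3L 10730656 with 2.49 ± 0.50 and 3R 21834454 with 2.43 ± 0.50 (SD, n = 3). With normexp these 5 values were 1.57, 1.37, 1.23, 1.57 and 1.04, and at a window half-width of 1000 bp they ran from 1.23 to 1.93.

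Leaving out replicate 1 changed the outcome for windows, though not for single probes, which stayed at 0 calls, with 12034 above 0 and 7078 below at an unadjusted p under 0.05. Without it, limma called 357 windows enriched and 0 depleted, and each of the 20 shifted draws gave 0 calls. The called windows with another within 1000 bp formed 96 regions. At an unadjusted p under 0.05, 25640 windows were then above 0 and 9584 below, against means of 14421 and 5085 in the shifted draws. The region with the highest mean over replicates 2 and 3 was 2L 14531478 to 14531911, with log2 ratios of 2.10 in replicate 2 and 3.61 in replicate 3. It was followed by 3L 10730127 to 10730656 with 2.55 and 2.98, 2L 4282791 to 4283351 with 1.90 and 3.18, X 2346567 to 2347718 with 2.27 and 2.70, and 3R 26396416 to 26396960 with 2.07 and 2.88. The adjusted p of limma in these regions was as low as 0.00599 at the one on 3L. Of the 357 windows, 117 were among the 248 shared by all 3 replicates where 0.189 would overlap by chance, although windows with high ratios in 2 replicates enter both lists. In replicate 1, which was not used for these calls, 337 of the 357, or 94.4%, lay above the median of that replicate. Of the 69 shared regions, 43 held a window called without replicate 1, as did 13 of the 15 strongest, the exceptions being X 2541610 to 2542089 and 3L 22437655 to 22437894. Of the 96 regions, 32 overlapped a shared region.

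Low signal in the mock limits what could be examined, at these regions and over the whole array. The filter on the mock left 58570 windows of 469196. Only 10 of the 69 shared regions could be examined with probes well above background in the mock of all replicates, of which 2 were shared again, and with a normexp background correction 10 of the 69 were found again. Of the 15 strongest, 2 were found again with normexp, 0 with the filter on the mock and 8 with spots above background in both channels. The filters left only 10 and 52 of the 69 regions testable. How many of the 15 were among those was not counted, so the 0 and the 8 are not out of 15 tested regions. The means of the 15 were 1.06 to 2.31 with normexp, against 1.88 to 3.16 at the 14 of them with spots above background in both channels. The offset of 50 used with normexp lowers the ratios of dim spots by construction, and its part in this fall was not separated. The sizes given thus depend on how dim spots are treated, including the choice of that offset. With probes well above background in the mock, 9 of the 15 had a value, from 1.63 to 3.26, the lowest at X 2189651 to 2190235. The values under the filter on both channels and under that on the mock average whatever probes remain. They were taken without the minimum of 3 probes per window, so they may rest on fewer. The 1 region without spots above background in both channels, 3L 22437655 to 22437894, had a value of 3.04 that rests in part on floor values.

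Over all windows the replicates shared little. The Pearson correlation between replicates across 1 kb windows was 0.08 for replicates 1 and 2, 0.14 for replicates 1 and 3 and 0.20 for replicates 2 and 3, and across single probes it was 0.04 to 0.11. Across windows of 20 kb it was 0.27 to 0.44 and across windows of 50 kb it was 0.37 to 0.49. Windows overlap and are not independent, so no p is given.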

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

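Everything on shared windows and regions, and the array weights, probe-length, background-spot and broad-window settings, was chosen after the data were seen. The limma counts of 0 stayed at 0 under all settings but those given next, and for single probes under all. This is no sign of stability, since the fit of 3 replicates found 0 of 50 simulated sites with 4 added, and stricter thresholds or other merging cannot raise a count of 0. Leaving out 1 replicate gave 0 to 357 enriched windows and 0 to 96 regions, the highest without replicate 1, whose spread is the largest. Array weights with the trend and robust options gave 33 enriched and 4 depleted windows and 3 regions, but 2702 enriched windows in a shifted draw, more than in the real data. A half-width of 10000 bp gave 3335 enriched windows and 147 regions, and 0 of both once each replicate's window means were centred. After that centring 40872 windows were above 0 and 14885 below at an unadjusted p under 0.05 (9697 and 3030 on average in shifted draws). A half-width of 25000 bp with scaled replicates gave 2202 enriched windows and 50 regions, and 55 windows and 4 regions once centred. The 248 shared windows and 69 regions became 50 and 11 with normexp, and 39 and 11 with probes well above background in the mock (58570 windows tested). They became 128 and 39 with spots above background in both channels (157791 tested), 147 and 40 at a half-width of 250 bp, and 470 and 33 at 10000 bp. Single windows count among the windows but form no region. At 25000 bp there were 19 regions with merging within 1000 bp. The top 2% held 560 windows and 138 regions, and the top 0.5% held 119 and 32. Pairs of replicates shared 407 to 991 windows and 103 to 269 regions, by construction. Apart from the narrower filters, the cause was not tested. The mean correlation between replicates over windows was 0.14, ranged from 0.083 without replicate 3 to 0.204 without replicate 1, and was 0.35 and 0.43 at half-widths of 10000 and 25000 bp. Loess, centring on the mode and the deposited log2 table shared a window at 69 of the 69 regions, and subtracting probe-length medians at 68. Centring on the mode only shifts each array by a constant, so it could hardly change ranks within a replicate and its count is no sign of stability. The deposited table holds the scanner's ratio of the same spots but is no plain shift of the values analysed. Both have array medians of 0, yet the table gave 11235 windows above 0 at an unadjusted limma p under 0.05, against 13859. As another ratio of the same intensities, it is still a weak check. The means of the 15 named shared regions, 2.93 to 3.49, were 1.06 to 2.31 with normexp and 1.39 to 2.67 at a half-width of 1000 bp. Of the 15, 2 were found again with normexp and 14 at 1000 bp. Signal over background limits which of the 69 regions can be examined, 10 with the filter on the mock and 52 with that on both channels. The GC correction, the gene-based alternatives and the scan batch as a block were not run.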

Other observations

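The 50 kb windows, the comparison of chromosomes and the shared windows below were chosen after the data were seen. At a half-width of 25000 bp, window centres in the top 1% of all 3 replicates formed 9 stretches when merged within 25000 bp. Merging within 1000 bp gave 19 regions. A stretch can thus hold centres that were not in the top 1%. The highest mean was at 3R 889987 to 911209, with a mean log2 ratio of 0.66 ± 0.44 (SD, n = 3), followed by X 2187449 to 2202764 with 0.64 ± 0.39, 2R 14173530 to 14215837 with 0.62 ± 0.46, 3R 18002143 to 18015672 with 0.62 ± 0.49 and 3R 12053098 to 12075123 with 0.62 ± 0.38. The other 4 were on 3L, at 2830746 to 2832520, 623572 to 631446, 16191036 to 16195514 and 747791 to 748827, with means from 0.54 to 0.59. Replicate 1 was the highest in all 9, with 1.11 against 0.24 and 0.63 in replicates 2 and 3 at 3R 889987 to 911209. Its mean over all 1 kb windows was 0.42, so the size of these means rests mostly on replicate 1. The stretches on X and on 3R from 12053098 held 3 of the 69 narrow shared regions, and the other 7 held none. All 9 were found again after subtracting probe-length medians, and 3 with spots above background in both channels. In 50 kb windows scaled and centred per replicate, limma gave 35586 windows above 0 and 11331 below 0 at an adjusted p under 0.05, and 0 in each of the 20 shifted draws. Scaled but not centred they gave 46537 above and 0 below, and neither scaled nor centred 0 and 0, so the counts depend on both steps, and the windows overlap heavily.

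Relative to the mean of all windows, chromosome 4 had a log2 ratio of -0.08, -0.04 and -0.13 in replicates 1, 2 and 3. The heterochromatic classes all lay below 0 in replicate 3 but did not move alike in replicate 1. 2R heterochromatin (2127 windows) had -0.04, -0.06 and -0.19, that of 3L (1917 windows) 0.01, -0.03 and -0.16, and that of 3R (1465 windows) 0.002, -0.05 and -0.17. Among the smaller classes, 2L heterochromatin (182 windows) had 0.21, 0.01 and -0.05. X heterochromatin (536 windows) had 0.25, -0.09 and -0.09, and Y heterochromatin (356 windows) -0.11, -0.03 and -0.03. The mitochondrial genome, with 43 windows, had 0.21, 0.14 and -0.52. These differences were not tested.

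The narrow shared regions are a pattern that the mock, the floor values or the dyes could produce without binding. The 20 shifted draws gave 4 shared windows at most against 248, which argues against chance overlap of replicates that each have local structure. Around windows picked on every other probe, the probes between them rose by at least 0.438 of what the picked ones did in each replicate (interval from 0.310 in the replicate with the lowest ratio), which argues against a bias of single probes, and subtracting probe-length medians left 251 shared windows. With spots above background in both channels, and the top 1% drawn anew, there were 128 shared windows, 811 times their chance number of 0.158. That argues against floor values as the whole cause, although only 27 of the 52 regions testable in that way were found again. With the top 1% drawn anew, normexp gave 50 shared windows and the filter on the mock 39, which were 107 and 666 times their chance numbers. Yet normexp found 10 of the 69 regions again and the filter on the mock 2 of the 10 testable, so the part of dim signal stays open. Binding of Ubx stays open as a hypothesis beside a bias of neighbouring sequence in dye or amplification, since no dye swap, no input and no discs without Ubx were analysed here.

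Swapping the channels of 1 replicate gives 4 orientations, too few for a share under 0.05. Only the real one, 1 of the 4, gave as many as 248 shared windows, and the highest other count was 4. All 4 orientations gave as many adjusted calls of the limma window fit, with 0 in the real one and 0 as the highest other.

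The correlation between replicates rose with window width, to 0.366 for the least correlated pair over 50 kb windows, and regional differences in base composition or in floor values could raise it without binding. Subtracting probe-length medians left 0.315 for the lowest pair, 86.0% of it (95% bootstrap interval over 73 blocks of 2000 kb from 82.7% to 89.1%), which argues against probe length as the whole cause. With spots above background in both channels the lowest correlation was 0.255, 69.6% of it with an interval from 62.9% to 77.2%, which spans the bound set for excluding floor values, so their part stays open. The other pairs rose, replicates 1 and 3 from 0.4205 to 0.4376 and replicates 2 and 3 from 0.4904 to 0.4956. This filter gave 246262 windows against 464389, with a lower minimum of probes, so unlike windows are compared. Base composition itself was not tested, and no biological explanation of the broad pattern was tested.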
